A study of Drosophila melanogaster with 2 samples.

How the data were processed

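The series holds transcription factor ChIP-seq of whole wandering larvae of the last instar that express a br-RJ product fused to GFP, precipitated with an antibody against GFP. There are 2 biological replicates of 1 group, per the labels, made from sonicated chromatin with a fragment range of 200 to 800 bp, per the labels. For each of the builds dm6 and dm3 the authors deposited a peak list per replicate and a list called on the pooled replicates, each of 30000 peaks prepared as input for the irreproducible discovery rate (IDR) step, and an optimal IDR set. Peaks were called against a control alignment, per the README deposited with each replicate, and that alignment is not analysed here. The aligner, the peak caller, its settings and the IDR cutoff are not given in the sources used here.

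The main measurement is the signal value of each peak that the authors deposited; its scale is not stated, so it was used to rank and filter peaks within a list, and levels in the pooled list and in a replicate's list are not on one scale. The lists also give the −log10 q value of each peak as the authors' peak caller wrote it, and this column is limited at its top. Checked on the files, the 6635 peaks of the optimal set were exactly the 6635 strongest of the pooled list by signal, and the same held for the 6860 of dm3. No read counts are in the lists, so depth is unknown and no counting interval was computed for signals.

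Gene positions came from Ensembl release 115 (annotation BDGP6.54), and sequence from the reference genome of the same assembly. Peaks on arms 2L, 2R, 3L, 3R, 4, X and Y were used, which held all 6635, and no peak was removed. In the optimal set 50 peaks repeat the interval of another peak with a summit of their own, and each was counted. No annotation of dm3 coordinates was used, and the dm3 lists entered counts, overlap and correlation only. Coordinates are 1-based on dm6.

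A gene counted as bound when a summit of the optimal set lay within 1000 bp of any of its annotated start sites. Each summit was classed, in this order, as promoter (within 500 bp of an annotated start site of a protein-coding gene), 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron or intergenic, and class shares were compared with 1000 circular shifts of the summits along each arm (two-sided). Replicates were compared by the share of the 6635 strongest peaks of one list with a summit within 100 bp in the other, with 1000 circular shifts (one-sided). Each of 25 gene lists was compared with all other protein-coding genes by Fisher's exact test (two-sided), adjusted by Benjamini-Hochberg over the lists with at least 5 genes. Signals of bound list genes were compared with those of other bound genes by a two-sided permutation test of the median with 100000 resamples. All 2080 strand-collapsed 6-mers, and separately 20 fixed sequences, were compared between a window of 50 bp to either side of the summit and a window of the same width centred 250 bp away, by an exact two-sided sign test with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Genes and peaks are not independent replicates, and these tests treat them as if they were.

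The lists, sequences, tests and alternatives were chosen before the data were examined. Older symbols were matched through the reference's synonyms, and 5 of them were assigned by hand. The genes named are the 20 protein-coding genes with the strongest peak near a start site, 22 genes fixed in advance, and for each list up to 4 bound members with the highest signal, or all where fewer than 6 were bound. The sequences named are the 10 6-mers with the highest ratio past the threshold and all 20 fixed ones. Features named by another choice are marked as such. For the named list members, the strongest summit of each replicate within 200 bp was looked up after the data had been seen. Alternatives covered the windows, the assignment of summits to genes, the background for 6-mers, peaks above the median signal, the dm3 lists, each replicate's own list in place of the optimal set, all circular shifts of list membership along the gene order, and logistic regression with log gene length and log number of start sites.

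Each test was run on simulated data. Each of the 3 gene list tests recovered 10 of 10 changed lists and called 0 of 100 unchanged ones, over 13968 genes. The changed lists held 40 genes each with an odds ratio of 6, and smaller odds ratios were not simulated. List members were drawn at random, and bound genes were drawn without regard to position, length or start sites. The simulation therefore does not measure calls that arise from clustered or long genes. The sign test recovered 5 of 5 planted 6-mers and made 0 calls among 2080 6-mers where none was planted. Its simulated windows and their background were shuffles of the same sequences, with equal base composition. Real summits and flanks differ in GC content (37.7% and 43.8%), so the simulation does not measure calls that arise from composition. The permutation test recovered a signal 4-fold higher in 1 list of 40 bound genes. Smaller changes and smaller lists were not simulated, so this check does not show what the test can miss in the real lists. The location test and the overlap measure were also tested on simulated data and recovered what was planted. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 20.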

Results

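Chromatin occupied by Broad was profiled in whole wandering larvae, in the last larval instar, of Drosophila melanogaster. Broad, the product of br, is a zinc finger transcription factor of the early response to the moulting hormone ecdysone. The larvae, of both sexes, came from a transgenic line in which the br-RJ product carries GFP at its C-terminal end, and chromatin was precipitated with an antibody against GFP. The series has 1 group with 2 replicates, which the labels call biological replicates, so no comparison between conditions was possible. The values are peak lists on the dm6 build, with a signal value per peak as the authors' peak caller gave it. The read depth of the replicates is unknown from these lists, and the 30000 peaks of each input list are a fixed number that does not measure depth.

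The first question was where in the genome the tagged Broad protein was found. The authors' optimal set, the peaks kept after the irreproducible discovery rate (IDR) step over both replicates, held 6635 peaks. Chromosome arms 2L, 2R, 3L, 3R and X carried 52.0, 49.2, 51.4, 48.9 and 48.5 peaks per Mb. The small arm 4 carried 10.4 per Mb (14 peaks), and Y had 0 peaks in the set. Signal values ran from 80.0 to 3635 with a median of 137. Peaks that overlap a neighbour were counted separately. The median peak was 430 bp wide, as in the whole pooled list, and the peaks of the optimal set covered 1.73% of the 7 arms. A share of 78.9% of the peaks stood at the highest −log10 q value in the list, 4.02, so that q value does not rank them.

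The strongest promoter signal belonged to a peak of 2881 at X from 2703678 to 2704097, between the divergent genes Ugalt, a UDP-galactose transporter, and eIF2Bbeta, a subunit of a translation initiation factor. Replicates 1 and 2 gave this peak signals of 1412 and 1513 in their own lists. The genes that follow were CG14100 (2833), CG1888 (2563), the pair PNPase and Gprk2 (2137), and Lk6 (2091), which encodes a protein kinase. Next came Chro, which encodes a chromodomain protein, with its neighbour Ssl1 (2063), then Tcs5 with CHMP2B (1911), and CG18549 (1811). The list of 20 genes ended with ph-p (1788), a Polycomb group gene, mRpS23 with CenG1A (1785), Pdrg1 with Pal1 (1765), larp (1721), and Pex11ab with CG8320 (1701). The peaks at these 20 genes lay within 500 bp of an annotated transcription start site (TSS), except that of Lk6, which was intronic. The highest signals of the whole set lay more than 1000 bp from a TSS and were chosen after their values were seen. They were 3635 in an intron of ush (2L from 480565 to 481394), which encodes a cofactor of GATA factors, and 3021 in an intron of CG11050 (2L from 6612393 to 6612926).

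The replicates were compared next. Of the 6635 strongest peaks of replicate 1, 4784 (72.1%) had a summit within 100 bp of a summit among the 6635 strongest of replicate 2. Circular shifts of one list gave 1.00% on average and 1.69% at most, and 0 of 1000 shifts reached the observed share (one-sided permutation p = 0.000999, the smallest that these shifts can give). The shared share was higher among stronger peaks, with 90% of the 100 strongest and 86.5% of the 1000 strongest shared, against 52.7% of all 30000. In the optimal set, 6181 peaks (93.2%) matched a peak in both replicate lists, and across them the signals of the replicates correlated with a Spearman rho of 0.786 and a Pearson r of 0.851 on the log2 scale. The optimal set comes from a list called on the reads of both replicates and passed the IDR step. These matches therefore arise in part by construction, and the correlations cover matched peaks only. Peaks are not independent replicates, so these correlations carry no p-value. The log2 ratio between replicates had an SD of 0.52 across peaks, and 94.2% of the peaks differed by less than 2-fold.

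**Figure D1:**
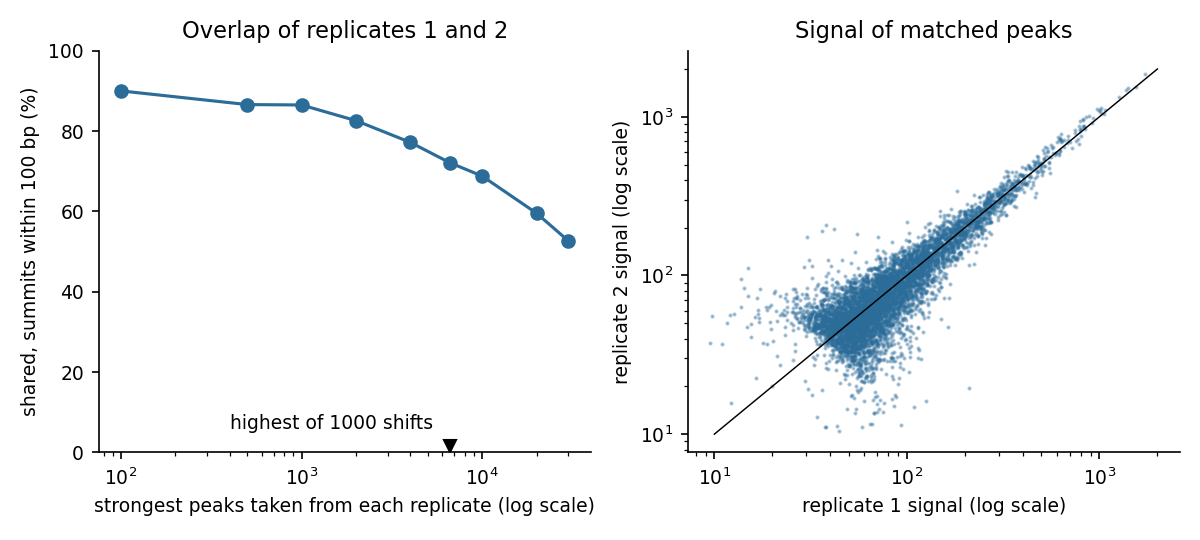
Left, share of the strongest peaks of replicate 1 with a summit within 100 bp among as many peaks of replicate 2 (y axis, %) against the number taken (x axis, log scale), falling from 90% at 100 peaks to 52.7% at 30000; the triangle is the highest of 1000 circular shifts, 1.69%. Right, signal of replicate 2 against replicate 1 (both log scales) for the 6181 matched optimal peaks, with the line of equality.

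Peak summits were concentrated at promoters and nearly absent from coding exons. Summits within 500 bp of a TSS made up 40.7% of the set (2702 peaks), 3.55 times the 11.5% found after circular shifts. Coding exons away from promoters held 17 summits (0.256%), against 13.9% after shifts, and 3′ untranslated regions held 0.859% against 4.50%. Introns held 39.6%, close to the 39.8% after shifts (adjusted permutation p = 0.85), and 5′ untranslated regions outside promoters held 0.739% against 0.797% (adjusted permutation p = 0.78). Intergenic sequence held 15.7% against 28.0%, and exons of other kinds 2.13% against 1.60% (adjusted permutation p = 0.017). For promoters, coding exons, 3′ untranslated regions and intergenic sequence the adjusted permutation p over the 7 classes was 0.0035, from an unadjusted p of 0.0020, the smallest that 1000 shifts can give in a two-sided test. The median distance from a summit to the nearest TSS was 980 bp, and 88.5% of summits lay within 10000 bp of one. The excess in other exons was not past the threshold among peaks above the median signal (ratio 1.23, adjusted permutation p = 0.27). With promoters taken as 250 bp, introns held more summits than after shifts (ratio 1.05, adjusted permutation p = 0.035), and with 1000 bp fewer (ratio 0.894, adjusted permutation p = 0.0028), as did 5′ untranslated regions (ratio 0.585, adjusted permutation p = 0.026).

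**Figure D2:**
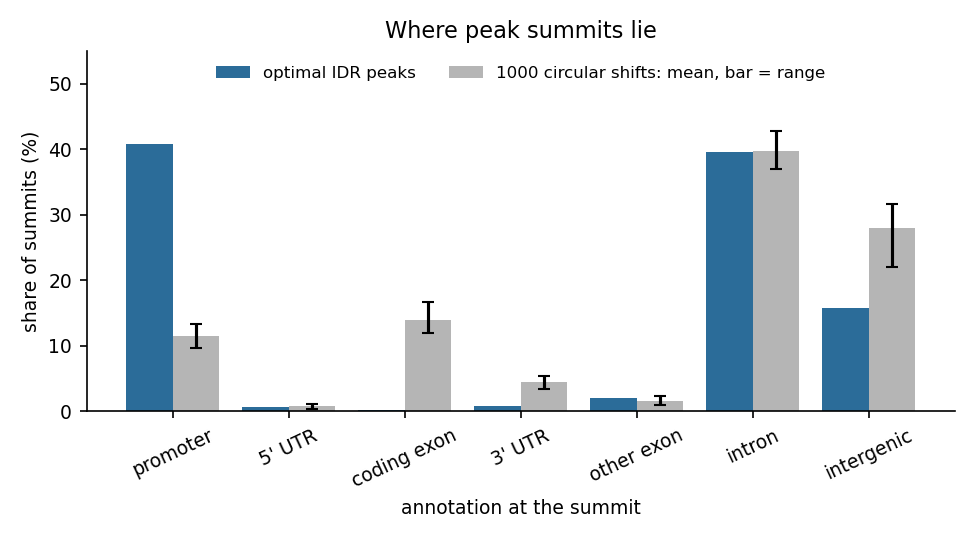
Share of the 6635 optimal summits in each annotation class (blue) and the mean share over 1000 circular shifts along each arm (grey bars, with black lines from the lowest to the highest shift); y axis in percent. Promoters hold 40.7% against 11.5%, and coding exons 0.256% against 13.9%.

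The ecdysone cascade was the next question, since br itself is one of its early genes. Of 33 cascade genes, 22 (66.7%) had a summit within 1000 bp of a TSS, against 24.3% of the 13968 protein-coding genes (odds ratio 6.25, 95% interval 2.90 to 14.3; adjusted p = 2.0e-06, Fisher's exact test). The highest signals within 1000 bp of a TSS, which are the values given for the members of every list, were at Eip75B, a nuclear receptor gene (727), Eip63F-1 (518), E23 (452), an ABC transporter gene, and the nuclear receptor gene Hr96 (450). Eip75B (3L from 17950953 to 18064696) held 33 peaks in its body or within 1000 bp of it. The strongest of these, with a signal of 1656 and rank 24 in the set, was in an intron at 18011647 to 18012147, 12087 bp from the nearest TSS. With log gene length and log number of start sites in a logistic model the odds ratio of the list was 2.65 (95% interval 1.21 to 5.80, n = 13968 genes, adjusted p = 0.034). With each summit given to the gene of the nearest TSS at any distance, the odds ratio was 13.5 (exact adjusted p = 8.3e-11). This last setting does not adjust for gene length.

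**Figure D3:**
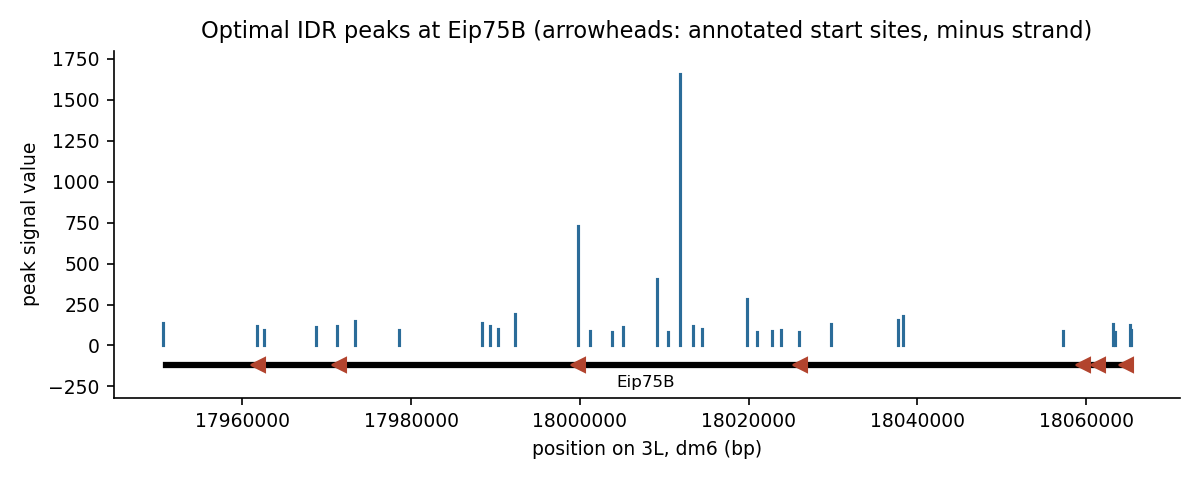
Optimal peaks at Eip75B on 3L (dm6), as vertical lines at their summits with the signal value on the y axis, and the gene below with arrowheads at its 7 annotated start sites. The tallest line, 1656, is intronic, and the second, 727, is at a start site.

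At br (X from 1575132 to 1664869), 10 peaks lay in the gene or within 1000 bp of it. The strongest within 1000 bp of a TSS had a signal of 224 (rank 1636; 104 and 135 in replicates 1 and 2), and the highest of the 10 had 246. These peaks also lie inside Mur2B, a gene that spans br. EcR and usp, which encode the subunits of the ecdysone receptor, had TSS peaks of 161 and 223, and EcR had 14 peaks in all with a maximum of 343 in an intron. Among the other genes of the ecdysone response, Eip74EF had a TSS peak of 190, Hr3 of 182 and ftz-f1 of 135, and the strongest peaks of these genes were intronic, with 247, 371 and 180. Kr-h1, a gene of the juvenile hormone response, had a TSS peak of 152, its strongest. Hr4 had no peak within 1000 bp of a TSS, but held 9 peaks, the strongest of 990 (rank 84) in an intron. Hr39 held 1 intronic peak of 91.8, and Eip93F had 0 peaks in the set. The glue genes Sgs3 and Sgs4, Fbp1, a fat body gene, and Ddc, which encodes dopa decarboxylase, had 0 peaks. Of the cell death genes fixed in advance, hid had a promoter peak of 444, and rpr and Dronc had 0. In the temporal series of neural progenitors, Imp had a TSS peak of 140 and chinmo of 97.9, and chinmo held 3 peaks with a maximum of 183 in an intron. Mmp1, a matrix metalloproteinase gene, had a TSS peak of 126, and Sb, a protease gene needed for disc eversion, had 0 peaks in the set.

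Apart from the ecdysone cascade, 3 of the 25 lists held more bound genes than other genes did. Ribosomal protein genes were bound in 66 of 92 cases (71.7%; odds ratio 8.03, 95% interval 5.02 to 13.2; exact adjusted p = 2.5e-20), with RpL7 (827), RpS27 (777), RpL34b (634) and RpS19b (556) at the top. Genes of the Notch pathway were bound in 16 of 29 (odds ratio 3.84, 95% interval 1.73 to 8.69; exact adjusted p = 0.0013), led by fng (481), E(spl)m7-HLH (396), numb (363) and aph-1 (338). At E(spl)m7-HLH the list of replicate 1 had no summit within 100 bp, and its strongest within 200 bp was 117 bp away (186, against 217 in replicate 2), and at numb the nearest was a weak one (38.1), with one of 149 at 102 bp (207 in replicate 2). Genes of epithelial morphogenesis were bound in 15 of 30 (odds ratio 3.12, 95% interval 1.42 to 6.85; exact adjusted p = 0.0057), led by RhoGEF2 (357), sqh (294), mbc (255) and Rok (227), which act on actomyosin contraction or cell shape. The call for epithelial morphogenesis was not past the threshold with gene length and start sites in the model (odds ratio 1.47, n = 13968 genes, adjusted p = 0.38), among peaks above the median signal (2.06, exact adjusted p = 0.23), or with the list of replicate 2 alone (2.34, exact adjusted p = 0.064).

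**Figure D4:**
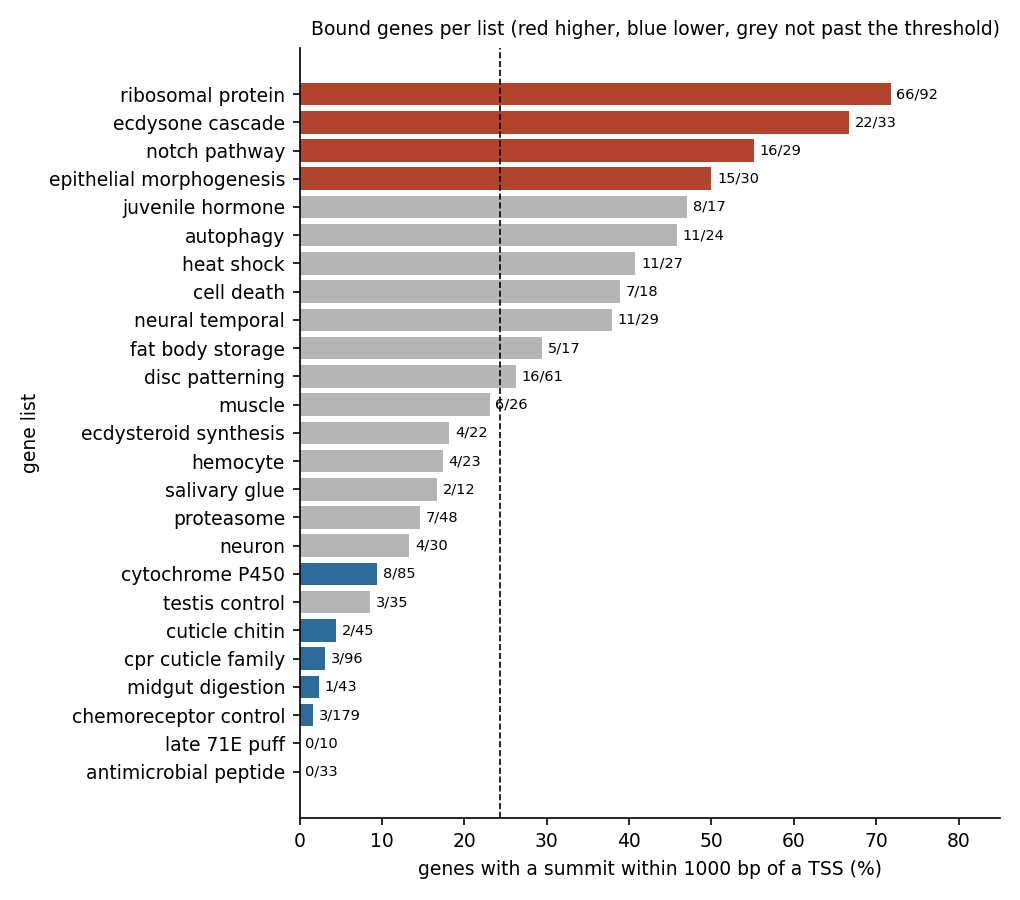
Share of the genes in each of 25 lists with a summit within 1000 bp of a TSS (x axis, %), with bound and total genes beside each bar. The dashed line is the 24.3% of all protein-coding genes, red and blue bars passed the threshold above and below other genes, as did antimicrobial peptide genes, whose bar is at 0, and the highest bar is the 71.7% of ribosomal protein genes.

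In 6 lists fewer genes were bound than among other genes. Chemoreceptor genes were bound in 3 of 179 (odds ratio 0.0522; exact adjusted p = 8.4e-17): Ir94h (317), Ir60e (154) and Gr63a (90.2). The Cpr and Twdl cuticle families had 3 bound of 96 (odds ratio 0.0995; exact adjusted p = 2.1e-07): Cpr72Eb (210), Cpr62Ba (122) and Cpr (149), the last of which encodes a P450 reductase and not a cuticle protein. Midgut digestive enzymes had 1 bound of 43, Mal-A5 (526; odds ratio 0.0738, exact adjusted p = 6.0e-04), and antimicrobial peptide genes 0 of 33 (95% interval of the odds ratio 0 to 0.367; exact adjusted p = 6.0e-04). Larval cuticle and chitin genes had 2 of 45, Cht7 (306) and Cht2 (123), with an odds ratio of 0.144 (exact adjusted p = 0.0022). Cytochrome P450 genes had 8 of 85 (odds ratio 0.321; exact adjusted p = 0.0023), with Cyp6u1 (595), Cyp310a1 (367), Cyp317a1 (232) and Cyp4d20 (197) highest. The midgut call was not past the threshold among peaks above the median signal (odds ratio 0.134, exact adjusted p = 0.051) or in the logistic model (0.116, n = 13968 genes, adjusted p = 0.067), and the P450 call was not past it among those stronger peaks (0.427, exact adjusted p = 0.10). Fisher's exact test treats neighbouring genes as independent. Circular shifts of list membership along the gene order also called all 10 lists, those bound more often included. Their adjusted permutation p was higher, from 8.9e-04 for chemoreceptor genes to 0.016 for the Notch list.

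The other 15 lists did not pass the threshold. Autophagy genes were bound in 11 of 24 (exact adjusted p = 0.060), with Atg17 (338), Atg2 (334), Atg18a (252) and Atg8a (181) highest and an odds ratio of 2.64. They passed the threshold with TSS windows of 500 bp (odds ratio 2.72, exact adjusted p = 0.036) and 2000 bp (3.35, exact adjusted p = 0.013), the nearest TSS (3.52, exact adjusted p = 0.0079), the gene body (3.75, exact adjusted p = 0.0037), the most upstream TSS (2.94, exact adjusted p = 0.026) and the list of replicate 1 alone (2.92, exact adjusted p = 0.020), and in the logistic model (3.001, n = 13968 genes, adjusted p = 0.032). They did not among peaks above the median signal (1.49, exact adjusted p = 0.54) or with the list of replicate 2 alone (2.59, exact adjusted p = 0.064), nor by circular shifts of list membership (adjusted permutation p = 0.077). Juvenile hormone genes were bound in 8 of 17 (exact adjusted p = 0.083), with Jheh1 (298), Kr-h1 (152), Jheh2 (143) and gce (138). The list of replicate 2 had no summit within 100 bp of those of Jheh1 and gce, and its strongest within 200 bp were 167 and 68.8. Juvenile hormone genes passed the threshold with a TSS window of 500 bp (odds ratio 3.38, exact adjusted p = 0.029). Heat shock genes were bound in 11 of 27 (exact adjusted p = 0.12), with Hsp27 (1688), Hsp83 (790), Hsp26 (548) and Hsc70-5 (274), and also passed it at 500 bp (odds ratio 2.62, exact adjusted p = 0.032). Cell death genes were bound in 7 of 18 (exact adjusted p = 0.23), with Diap1 (785), Cyt-c-d (563), hid (444) and Drice (136). Neural temporal genes were bound in 11 of 29 (exact adjusted p = 0.19), with lola (568), brat (377), mamo (236) and grh (216). The summit nearest to that of lola in replicate 2 was 109 bp away (322). Imaginal disc patterning genes were bound in 16 of 61 (exact adjusted p = 0.80), with bowl (793), aos (196), C15 (187) and net (136). They passed the threshold when each summit was given to the gene of the nearest TSS at any distance (odds ratio 7.17, exact adjusted p = 1.6e-12). They also passed it when the whole gene body counted (odds ratio 3.17, exact adjusted p = 3.8e-05). Neither setting adjusts for gene length. The direction turned among peaks above the median signal (0.291, exact adjusted p = 0.080), and in the logistic model (0.519, n = 13968 genes, adjusted p = 0.067), neither past the threshold. Neural temporal genes also passed with the nearest TSS (odds ratio 3.19, exact adjusted p = 0.0059), and turned direction in the logistic model (0.634, n = 13968 genes, adjusted p = 0.37) and with the most upstream TSS (0.903, exact adjusted p = 1), neither past the threshold.

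Fat body storage genes were bound in 5 of 17 (exact adjusted p = 0.71): Apoltp (197), bmm (169), Adh (148), FASN1 (143) and Lsd-1 (80.1). At Adh the strongest summit of replicate 1 within 200 bp was 117 bp away (72.9). Muscle genes were bound in 6 of 26 (exact adjusted p = 1), with Msp300 (811), Zasp52 (232), Mef2 (136) and Tm1 (129). Neuronal genes were bound in 4 of 30 (exact adjusted p = 0.27): elav (751), Syx1A (241), Csp (185) and futsch (94.7). In the logistic model both the muscle (odds ratio 0.275, n = 13968 genes, adjusted p = 0.032) and the neuronal list (0.152, adjusted p = 0.0041) were bound less often. With TSS windows of 500 and 2000 bp, the nearest TSS or the gene body the muscle ratio was above 1, at most 1.19 (exact adjusted p = 0.72), and not past the threshold. Ecdysteroid synthesis genes were bound in 4 of 22 (exact adjusted p = 0.71): woc (188), shd (130), mld (98.4) and Fdx1 (96.1). At woc the nearest summit of replicate 2 was a weak one (31.5), with one of 154 at 119 bp. Hemocyte genes were bound in 4 of 23 (exact adjusted p = 0.71): ush (205), NimB3 (160), Ance (149) and PPO3 (138). Proteasome genes were bound in 7 of 48 (odds ratio 0.530, 95% interval 0.20 to 1.19; exact adjusted p = 0.19), with Rpn5 (402), Rpt5 (284), Rpn11 (123) and Rpn2 (117). Testis genes were bound in 3 of 35 (exact adjusted p = 0.060): Mst36Fa (151), topi (101) and can (100.02), with an odds ratio of 0.291. They were bound less often than other genes with TSS windows of 500 bp (odds ratio 0, exact adjusted p = 0.0026) and 2000 bp (0.223, exact adjusted p = 0.012), the nearest TSS (0.180, exact adjusted p = 0.010), the gene body (0.250, exact adjusted p = 0.023) and the list of replicate 1 alone (0.176, exact adjusted p = 0.012). They did not pass with the most upstream TSS (0.324, exact adjusted p = 0.12), among peaks above the median signal (0.166, exact adjusted p = 0.11), with the list of replicate 2 alone (0.286, exact adjusted p = 0.064), by circular shifts of list membership (adjusted permutation p = 0.12) or in the logistic model (0.330, n = 13968 genes, adjusted p = 0.12). Glue genes were bound in 2 of 12 (exact adjusted p = 0.80), Sgs5 and Sgs5bis, which share a peak of 142, and the late genes of the 71E puff in 0 of 10 (exact adjusted p = 0.19).

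Among bound genes, peaks at ribosomal protein genes had a median signal of 223, against 164 at other bound genes, a ratio of 1.37 (adjusted p = 0.077, permutation test). Disc patterning genes had a median of 104 and a ratio of 0.632 (adjusted p = 0.18, permutation test). By this permutation test 0 of 14 lists passed the threshold, and 2 had an unadjusted p below 0.05. The ribosomal protein list passed it with a TSS window of 500 bp (ratio 1.41, adjusted permutation p = 0.034). It also passed by rank in the list of replicate 1 (ratio of median reciprocal ranks 1.61, adjusted permutation p = 0.049), where a ratio above 1 means stronger peaks.

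Sequence at the summits was richer in A and T than sequence beside them: GC content was 37.7% in the 101 bp around summits and 43.8% in flanks centred 250 bp away. Of all strand-collapsed 6-mers, 492 were more frequent at summits and 787 less frequent (exact sign test, adjusted p under the threshold of 0.05). The highest ratios were those of ACTATC (5.02% of summits against 2.13% of flanks, 2.36-fold), CGATAG (2.16), ATCTAA (2.14), AACTAT (2.11), ATATTA (2.11), ATACTA (2.06), TTTAAA (2.04), TAGCTA (2.03), CTAATA (1.99) and TACTAA (1.96), all with an adjusted p of 2.0e-07 or less. Against dinucleotide-shuffled copies of the summit windows 318 6-mers were higher, of which 88 were among the 492. CGATAG stayed at 2.21 (exact adjusted p = 8.0e-15) and ACTATC at 1.56 (exact adjusted p = 2.3e-06) against the shuffled copies. ATCTAA (0.895), CTAATA (0.916) and TACTAA (0.816) turned to below 1, and ATACTA and TAGCTA were no longer past the threshold. Against flanks, CGATAG had a ratio of 2.92 at summits within 500 bp of a TSS, but below 1 at those beyond 1000 bp.

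Of 20 sequences fixed in advance, 10 differed between summits and flanks when adjusted over the list alone. The DRE sequence TATCGATA, bound by the factor DREF at promoters of widely expressed genes, was 3-fold more frequent at summits (1.31% against 0.437%; exact adjusted p = 2.2e-07), and its core ATCGAT 1.55-fold (exact adjusted p = 4.2e-06). The candidate cores of Broad sites were held from background knowledge and not from these data. They were GACAAA (candidate Z1), CTATTA (Z2), AAACTA (Z3) and TAAACAAA (Z4). Which of them the tagged br-RJ product would bind was not established. CTATTA had a ratio of 1.66 (exact adjusted p = 2.2e-09) and AAACTA 1.62 (exact adjusted p = 5.6e-16), while GACAAA (0.878) and TAAACAAA (1.11) were not past the threshold. The forkhead core TAAACA (1.38) and the homeodomain sequence TTAATTA (1.30) were also higher, as was the control sequence AAAAAA (1.25, exact adjusted p = 9.8e-11). Lower at summits were the GAGA factor core GAGAG (0.815), the repeat CACACA (0.649) and the E-box CACGTG (0.632). The nuclear receptor site AGGTCA (0.939), AACCGGTT (0.545) and ACCGGT (0.679) of Grainyhead, CAGGTAG of Zelda (0.619), TGACTCA of AP-1 (0.901), the E-box CAGCTG (1.14), GGAATG of Scalloped (0.841) and the Mad-like GGCGCC (1.28) were not past the threshold. Against the shuffled copies TATCGATA (6.69, exact adjusted p = 3.0e-14), ATCGAT (2.40, exact adjusted p = 3.8e-18) and TAAACA (1.21, exact adjusted p = 4.9e-05) were also higher. Against the same copies GAGAG (1.56), CACACA (1.5), CAGCTG (2.55), TAAACAAA (1.53) and GGCGCC (1.45) were higher, CTATTA (0.844), AAAAAA (0.888), AGGTCA (0.633) and GACAAA (0.799) lower, and AAACTA (1.09, exact adjusted p = 0.13), CACGTG (0.688, exact adjusted p = 0.057) and TTAATTA (0.858, exact adjusted p = 0.062) not past the threshold. With flanks 500 bp away, ATCGAT (1.22, exact adjusted p = 0.053), TTAATTA (1.17, exact adjusted p = 0.11), GAGAG (0.955, exact adjusted p = 0.36) and CACGTG (0.705, exact adjusted p = 0.11) were not past the threshold.

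The sequences at promoter and distal summits differed in the values measured, though the difference itself was not tested. At the 2702 summits within 500 bp of a TSS, TATCGATA was 4-fold more frequent than in flanks (3.11% against 0.777%; exact adjusted p = 5.3e-09), CTATTA had a ratio of 1.31 (exact adjusted p = 0.072) and AAACTA 1.15 (exact adjusted p = 0.20). At the 3299 summits more than 1000 bp from any TSS, AAACTA had a ratio of 2.40 (12.4% against 5.15%; exact adjusted p = 2.7e-24), CTATTA 2.45 (exact adjusted p = 1.5e-12) and TAAACAAA 1.71 (exact adjusted p = 0.0034), and TATCGATA occurred in 0.0606% of windows against 0.121% (exact adjusted p = 0.69). The control AAAAAA was also higher at distal summits (1.40, exact adjusted p = 1.5e-12) and at promoter summits (1.21, exact adjusted p = 0.0032), and TAAACA (1.68, exact adjusted p = 1.5e-12) and TTAATTA (1.57, exact adjusted p = 8.4e-04) were higher at distal ones. The candidate core GACAAA was lower at distal summits (0.805, exact adjusted p = 0.032). Other 6-mers had higher ratios at distal summits than CTATTA and AAACTA, among them TACCTA (3.07), TAGTAA (2.94) and ATATTA (2.82). Over all summits CTATTA was less frequent than in shuffled copies (0.844), and distal summits were not compared with shuffled copies separately. The E-box CAGCTG was more frequent than in flanks at promoter summits (ratio 1.47, exact adjusted p = 0.0026) and less frequent at distal ones (0.675, exact adjusted p = 0.0034), and TGACTCA had a ratio of 2.29 at promoter summits (exact adjusted p = 0.032). The number of higher 6-mers was 137 at promoter summits and 515 at distal ones, and of lower ones 127 and 787.

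**Figure D5:**
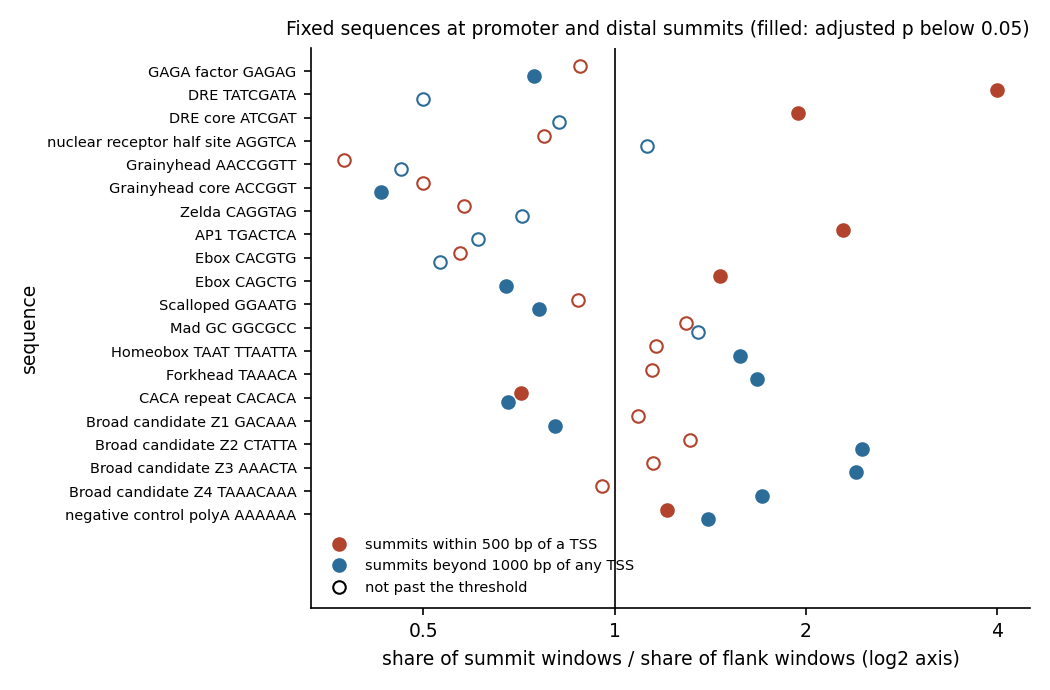
Ratio of the share of summit windows to the share of flank windows holding each of 20 fixed sequences (x axis, log2), at summits within 500 bp of a TSS (red) and more than 1000 bp from any TSS (blue); filled points have an adjusted p under 0.05 by exact sign test. TATCGATA stands at 4 near start sites, and CTATTA, AAACTA and the control AAAAAA at 2.45, 2.40 and 1.40 away from them.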

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

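The values in this part were chosen after the peak lists had been seen. The pooled list held 23365 peaks that are not in the optimal set. They entered no comparison between lists, classes or sequences in the Results, but are used under Other observations below. Of these 23365, 9549 (40.9%) had a summit within 100 bp in the lists of both replicates. The pooled list was called on the reads of both replicates, so such matches arise in part by construction. Circular shifts gave a mean of 513 and a highest of 670, and do not allow for these shared reads. The signals of these peaks ran from 16.2 to 80.0 with a median of 42.9. Promoters held 23.5% of them, against 11.5% over circular shifts, and coding exons 1.46% against 13.8%.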

How the results depend on the processing

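None of the alternatives in this part was added after the data were seen. Of 77 values that answer a comparison, 65 were labelled as the same as in the Results and 12 as moved. For counts this label rested on the size of the change and not on a direction. For the Spearman rho it rested on a bootstrap interval of 0.772 to 0.799 (1000 draws). For the replicate overlap it rested only on a share above that of the circular shifts, with a permutation p below 0.05. Any overlap far above the shifts was thus labelled the same, whatever its size. Of 633 values for single lists, sequences or classes, 509 stayed and 25 were no longer past the threshold. A further 41 came past it and 58 changed direction, of which 44 were past it in neither setting. Taking the strongest 6635 peaks of the pooled list changed nothing, by construction, and its values are counted among those that stayed the same. The replicate overlap ran from 57.4% (summits within 50 bp) to 86.5% (1000 strongest), each with a permutation p = 0.000999, the smallest possible. No paired analysis was possible because the series has 1 group. Depth is unknown, so its effect was not tested. The logistic model gave no value for antimicrobial peptide and late 71E genes, with 0 bound.

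The peak count was 3317 above the median signal, by construction. The Spearman rho was 0.830 with summits matched within 50 bp, 0.767 within 200 bp and 0.828 above the median signal. Lists bound more often numbered 7 with a window of 500 bp and 7 with the nearest TSS, and all 10 lists called in the report were called in both. The 6-mers numbered 318 higher and 477 lower against shuffled windows, and 137 and 127 at the 2702 summits within 500 bp of a TSS. The signal test called 1 list with a window of 500 bp and 1 by rank in replicate 1. Apart from the peak count, the cause of these changes was not tested.

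The values that changed direction follow, and the cause was not tested. The intron ratio was 1.05 with promoters of 250 bp. For lists, the odds ratio of muscle was 1.14 at 500 bp, 1.06 at 2000 bp, 1.09 with the nearest TSS and 1.19 over the gene body. Hemocyte genes had 1.27 at 2000 bp, 1.05 with the nearest TSS and 1.19 above the median signal. Disc patterning had 0.921 at 2000 bp, 0.938 with the most upstream TSS, 0.291 above the median signal and 0.519 in the logistic model. Fat body genes had 0.994 at 2000 bp and 0.968 in the logistic model, neural temporal genes 0.903 with the most upstream TSS and 0.634 in the logistic model, and glue genes 1.13 above the median signal and 1.23 in the logistic model.

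For sequences, AACCGGTT had 1.13 with a 25 bp window, 1.09 with the flank at 500 bp and 2 against shuffled windows. GGCGCC had 0.957 with a 100 bp window and 0.965 with the flank at 500 bp, TAAACAAA 0.973 with a 100 bp window and 0.957 near a TSS, and CAGCTG 0.962 with the flank at 500 bp, 0.805 above the median signal and 0.675 at distal summits. Against shuffled windows ATCTAA had 0.895, CTAATA 0.916, TACTAA 0.816, GAGAG 1.56, TGACTCA 1.25, TTAATTA 0.858, CACACA 1.5, CTATTA 0.844 and AAAAAA 0.888. At distal summits CGATAG had 0.944, TATCGATA 0.5, ATCGAT 0.816 and AGGTCA 1.12. Near a TSS TGACTCA had 2.29 and GACAAA 1.09.

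For peak signal, the Notch ratio was 0.857 at 500 bp, 0.866 by rank in replicate 1 and 0.967 by rank in replicate 2. Ratios by rank are of median reciprocal ranks. Neural temporal genes had 1.02 at 2000 bp and 1.08 by rank in replicate 1, proteasome genes 1.41 at 2000 bp, and P450 genes 0.972 by rank in replicate 1. With 1 replicate left out, the lowest and highest values were 0.967 and 1.04 for 5′ untranslated regions, 0.460 and 1.15 for ecdysteroid synthesis, 0.910 and 1.13 for disc patterning, 0.897 and 1.27 for fat body genes, 0.868 and 1.03 for AGGTCA, 0.967 and 1.09 for TGACTCA, and 0.946 and 0.976 for CAGCTG.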

Other observations

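The counts per gene, by peak rank and by distance from the summit in this part were chosen after the data were seen, and the tests of explanations were planned before their results. Eip75B held the most peaks of the optimal set, 33 in its body or within 1000 bp. It was followed by sbb (26), kirre (23), CG1677 (21), shn (21), which encodes a zinc finger factor of the Dpp pathway, Tet (19), Svil (18) and ush (17). Raf (16), a kinase gene of the MAP kinase pathway, tkv (15), which encodes a Dpp receptor, and EcR (14) were also among the 15 genes with the most peaks. Of these 15, Mnt had the most per 10 kb (4.39), followed by shn (3.48).

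The share of promoter summits fell with rank in the pooled list, from 48.6% of the 1000 strongest peaks to 14.75% of the peaks beyond rank 20000, while the share in coding exons rose from 0.1% to 3.71%. Any coding sequence, promoters included, held 0.648% of the optimal summits (43 peaks), 1.24% of positions 100 bp to their right, 4.73% at 200 bp and 21.4% at 2000 bp. Coding sequence made up 16.6% of the arms, and 10.5% of random positions weighted to the GC content of the summits.

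Lists with a larger share of bound genes could reflect longer genes with more start sites. With both in the model, 3 of the 4 lists kept an interval above 1, which argues against this as the whole cause for those 3. For ribosomal protein and Notch genes the odds ratio rose, from 8.03 to 9.44 and from 3.84 to 4.18. Length and start sites thus took up none of their excess. For the ecdysone cascade it fell from 6.25 to 2.65 (1.21 to 5.80), so they may account for part of that excess. The epithelial morphogenesis list fell from 3.12 to 1.47 (0.692 to 3.12), an interval that leaves the matter open for that list. Uptake of open or highly transcribed promoters without sequence preference was also tested, and the ribosomal protein list had an odds ratio of 8.03 (5.02 to 13.2), as that explanation needs. It stays open. Proteasome genes had an odds ratio of 0.530 and were not past the threshold. Expression and open chromatin were not measured here for the genes of either list, so neither list decides this explanation. The series has 1 group, and no biological explanation was tested.

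Base composition may account for many of the 6-mers that were more frequent at summits. Of the 492, 17.9% were also higher against dinucleotide-shuffled copies of the same windows, and 101 were lower. CGATAG and ACTATC were among those higher in both. No biological explanation was tested.

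Extra copies of the br region, if the tagged transgene carries them, could raise the signal along br. Pooled-list peaks outside the optimal set numbered 0.613 per kb of br, above the 95th percentile (0.563) of 193 genes of similar length, whose median was 0.184. This is what the explanation needs, but Eip75B (0.721), cv-c (0.689) and dally (0.675) were denser, and the strongest optimal peak at br, 246, ranked 1394. Dense binding at br without extra copies was not tested and stays open.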
